A study of Homo sapiens with 10 samples.

How the data were processed

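Gene expression was measured on Affymetrix arrays in 10 RNA samples of human cell lines. BjhTERT are human foreskin fibroblasts kept dividing by an introduced telomerase gene (TERT). PC3 is a prostate cancer cell line, here carrying the red fluorescent protein mRFP. Per the labels, PC3 cells were plated on a fibroblast monolayer 4 days old at 1 tumor cell to 30 fibroblasts, and both cell types were separated by fluorescence-activated cell sorting (FACS) after 6 days. From each preparation 150 ng of total RNA was labelled. The fibroblasts were the parental line, a control line treated with virus, and a line in which RHOA, the gene of a small GTPase that controls actin stress fibres and contraction, was knocked out. Each line was measured alone and after co-culture, and PC3 was measured alone and after co-culture with each of the 3 lines. Each condition had 1 array, and the number of arrays limits the precision.

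The deposited table holds log2 expression values. According to the submitters' processing notes, they were made with Affymetrix Expression Console 1.3.1 and RMA. It holds 53617 transcript clusters and 10 columns. The values ran from 1.65 to 14.06, and the array medians lay between 3.41 and 3.46. Raw intensities were not analysed here. The genome build is not given in the sources used here, and no positions are printed. The supplied annotation gave 1 gene symbol for 23871 transcript clusters, several for 1842 and none for 27904. A table of current gene names updated the symbols of 90 transcript clusters. Where several transcript clusters had the same symbol, the 1 with the highest mean over all arrays was kept, which left 22395 genes. Values were used as deposited, with no further normalization. For each cell type, a gene was tested if its highest array reached 3.43, the median of all values, which left 17409 genes in fibroblasts and 16690 in PC3.

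Linear models were fitted with limma 3.58.1 in R 4.3.3 (with the packages statmod 1.5.0 and, to read the data, data.table, version 1.17.8), with moderated variances (eBayes without trend) and Benjamini-Hochberg adjustment within each comparison. All tests were two-sided, and a gene passed at an adjusted p under 0.05. The co-culture effect in fibroblasts was fitted with the line as a block. The 3 line contrasts were the knockout against both other lines, the knockout against the virus control, and the virus control against the parental line, each with the culture as a block. These fits left 2 residual degrees of freedom. The difference in co-culture response between the knockout and the other lines left 1. PC3 after the 3 co-cultures was compared with PC3 alone (2 residual degrees of freedom), and PC3 after the knockout line with PC3 after the other lines (1). In the fibroblast fits line and culture were both fitted, so the spread was how far the change with co-culture differed between lines, and for the difference in response between the 2 lines with RHOA. In the PC3 fits it was the spread between co-cultures with different lines. No condition was repeated, so variation between cultures of the same kind was not measured. PC3 alone was also compared with the fibroblast lines alone.

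The rule for named genes was written before the data were examined. It took the 10 highest and the 10 lowest differences among the genes that passed and had the same sign in every pair of arrays behind the comparison. Where fewer than 10 passed, the list was filled with the genes whose smallest pair difference was largest, which are said to be chosen by size. It added up to 4 members of each gene list described, and RHOA, RHOB, RHOC, ACTA2, CXCL12, CXCR4, IL6 and CXCL8 always. A set of 26 gene lists was fixed at the same time, with 671 genes measured. Lists with at least 5 genes past the filter were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. For each list the count of genes past the test was also taken with the p values adjusted over the list alone. A list of small nucleolar and Cajal body RNAs was added after seeing the data and was not part of the camera adjustment.

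The share of RNA from the other cell type was estimated in each co-cultured array from marker genes. These reached at least 9 on the log2 scale in the other cell type alone and lay at least 4 above every array of the own cell type alone, which gave 24 markers of PC3 and 50 of fibroblasts. Each marker gave an implied share on the linear scale, and the median and quartiles were taken. After seeing the data, the median share was also subtracted on the linear scale, and genes for which the other cell type made up more than 50% of the signal were left out. Also after seeing the data, a gene was called above the mixture level where each of the 3 co-cultured arrays exceeded its own line's RNA plus the upper quartile share of the other cell type by at least 1 on the log2 scale. Genes lying at least 1 on the log2 scale outside both cell types in all 3 co-cultures were listed in the same way.

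The fits were tested on simulated data in which 200 genes were given known differences. At a difference of 1 on the log2 scale, the fits recovered 97.0% of the changed genes for the fibroblast co-culture effect, 89.6% for the knockout against both lines, 68.7% for the knockout against the virus control, 80.6% for the virus control against the parental line, 25.4% for the difference in response, 55.2% for PC3 and 76.1% for the PC3 partner comparison. At a difference of 2 every fit recovered at least 98.5%. Of the calls in that test, 27 of 225 were false for the fibroblast co-culture effect, 21 of 214 for the knockout against both lines, 15 of 194 for the knockout against the virus control, 22 of 209 for the virus control against the parental line, 28 of 177 for the difference in response, 10 of 180 for PC3 and 67 of 251 for the PC3 partner comparison. In a test with mixed profiles, shares of 12%, 6% and 4% in fibroblasts were estimated as 11.8%, 6.34% and 4.09%.

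Alternatives chosen before the data were examined were median centring, renewed quantile normalization, cyclic loess, no filter, a stricter filter on the mean, averaging of the transcript clusters of a gene, an intensity trend, robust eBayes, 1 fit of all 10 arrays, leaving out each array or line, no block for the line, the number that ends the label code (5 or 7) as a covariate, each culture alone, and leaving out genes that differ between the cell types. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.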

Results

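Expression was measured on 10 arrays, 6 from fibroblasts and 4 from PC3 prostate cancer cells. The fibroblasts were parental BjhTERT cells, a control line treated with virus and a line with RHOA knocked out, each alone and after co-culture with PC3. There was 1 array per condition and no replicate. In the fibroblast fits of co-culture and of line, the spread behind the p values is how far the change with co-culture differed between lines. Array medians lay between 3.41 and 3.46 on the log2 scale. Correlations across genes were 0.9716 to 0.9859 between fibroblast arrays, 0.9821 to 0.9888 between PC3 arrays and 0.8809 to 0.9206 between the cell types.

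A first comparison asked which genes tell the cell types apart when each was grown alone. PC3 held more RNA of the keratin KRT75, higher by 7.28 (SE 0.30), the 14-3-3 protein SFN, higher by 6.65 (SE 0.26), and the desmosomal cadherins DSC2 and DSG2, higher by 6.46 and 6.32. Differences were -7.78 (SE 0.49) for the gelatinase MMP2, -7.38 for the collagen-binding proteoglycan LUM and -7.02 for the proteoglycan BGN, which fibroblasts held more of. Where the lower cell type lay below the median of all values (3.43), as for DSC2 at 2.83 to 3.03 in fibroblasts and MMP2 at 3.01 in PC3, these differences are lower bounds. TERT, the telomerase gene introduced into these fibroblasts, lay at 11.51 to 11.91 in the 3 lines alone, and PC3 alone differed by -6.75 (SE 0.24). In limma, 1731 genes were higher in PC3 and 1303 lower at an adjusted p under 0.05, among 17126 tested.

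RNA of the other cell type was measurable in the sorted cells. All 24 PC3 marker genes were higher in each co-cultured fibroblast array than in the same line alone, with a median implied share of PC3 RNA of 11.7% in the parental line (quartiles 8.28% and 13.8%), 5.74% in the virus control (4.36% and 6.92%) and 4.48% in the knockout (2.38% and 6.17%). In PC3, 40 of the 50 fibroblast markers were higher after the parental line than in PC3 alone, and all 50 after each of the other lines. They gave a median share of 0.514% after the parental line (quartiles 0.232% and 1.18%). It was 3.77% after the virus control (2.86% and 4.85%) and 4.22% after the knockout (3.27% and 6.93%). TERT lay at 6.06, 7.99 and 8.49 in PC3 after these co-cultures, or 1.06, 2.99 and 3.49 above PC3 alone.

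**Figure D1:**
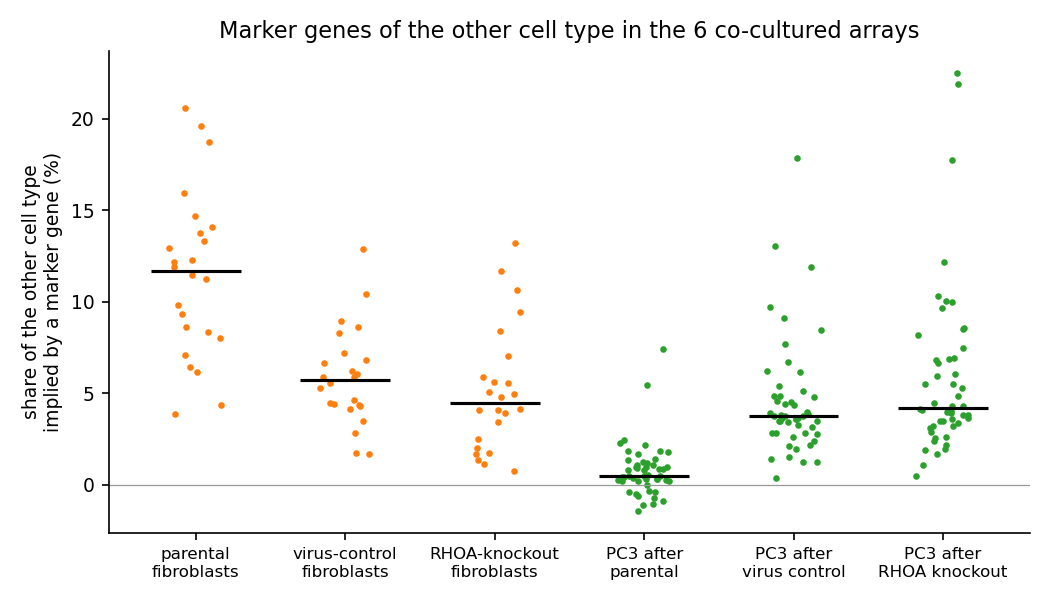
Share of RNA from the other cell type (percent) implied by each marker gene in the 6 co-cultured arrays, with 1 point per marker and a black line at the median. Medians run from 4.48% to 11.7% in fibroblasts and from 0.514% to 4.22% in PC3.

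The comparison of fibroblasts after and before co-culture asked how stromal cells respond to tumor cells. DHRS3, a retinaldehyde reductase, rose most, by 3.98 on the log2 scale (SE 0.17, higher in 3 of 3 lines), to 7.74 to 8.02 against 7.37 in PC3 alone. The transcript cluster of the microRNA gene MIR21 rose by 3.02 (SE 0.19), the olfactomedin OLFM2 by 2.94 (SE 0.37) and TGFB2, a ligand of the TGF-beta family, by 1.89 (SE 0.15). Expression fell by 2.45 on the log2 scale (SE 0.19) for the small nucleolar RNA SNORA2A, by 2.31 (SE 0.35) for the immediate-early transcription factor FOSB, by 2.05 (SE 0.23) for PTX3, a secreted pattern recognition protein, and by 1.68 (SE 0.19) for the matricellular protein CCN3. CXCL12, the chemokine ligand of CXCR4, fell by 1.08 (SE 0.15, adjusted p = 0.0298), from 9.67 to 8.62, 8.95 to 7.74 and 8.88 to 7.91.

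Other genes with large increases were ones that PC3 expresses at high level. PI3, an elastase inhibitor of epithelia, rose by 3.66, SFN by 3.50, the tumor surface glycoprotein CDCP1 by 3.37, the decoy receptor IL13RA2 by 3.24, the neurofilament gene NEFL by 3.10, the annexin ANXA10 by 3.02 and the T-cell receptor segment TRBC2 by 2.69. Of the 93 genes that rose, 57 were at least 1 higher on the log2 scale in PC3 alone than in fibroblasts alone, as were 9.05% of all genes tested, and the share of PC3 RNA in these arrays was 4.48% to 11.7%. Of these 57 genes, 22 were markers used for that share, and of the other 35 only DHRS3 lay above the mixture level. Further named decreases were -1.58 for the stress-induced factor ATF3, -1.53 for SPHKAP, -1.46 for LCE2A, -1.42 for the EGF-family ligand EREG, and -1.33 for both SCARNA3 and TMTC1. PC3 alone was lower than fibroblasts alone by at least 1 on the log2 scale for 13 of the 16 genes that fell. A PC3 share of 11.7% can take away at most that part of a gene's signal, which is less than any decrease named here. Among the genes tested in PC3, which are not the same set, 8.05% were lower in PC3 alone by that much.

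Above the mixture level in all 3 lines lay 24 genes, which were chosen after their values were seen, and all 24 passed the test. They included TGFBI, an extracellular protein induced by TGF-beta, higher by 1.53 (SE 0.18), CCN4, a WNT-induced matricellular protein, by 2.56 (SE 0.42), the collagen gene COL5A3 by 1.17, the chemokine CCL2 by 1.39, the endosulfatase SULF1 by 1.75 and the transglutaminase TGM2 by 1.21. The metalloproteases ADAMTS14 and ADAMTS15 (1.53 and 1.22), the pregnancy-associated protease PAPPA (0.97) and the prostacyclin synthase PTGIS (1.81) were among them too. PC3 alone held less of 21 of these 24 genes than fibroblasts alone. In 14 of them the co-cultured fibroblasts exceeded both their own line and all 4 PC3 arrays by at least 1 on the log2 scale, and no gene lay as far below both.

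**Figure D2:**
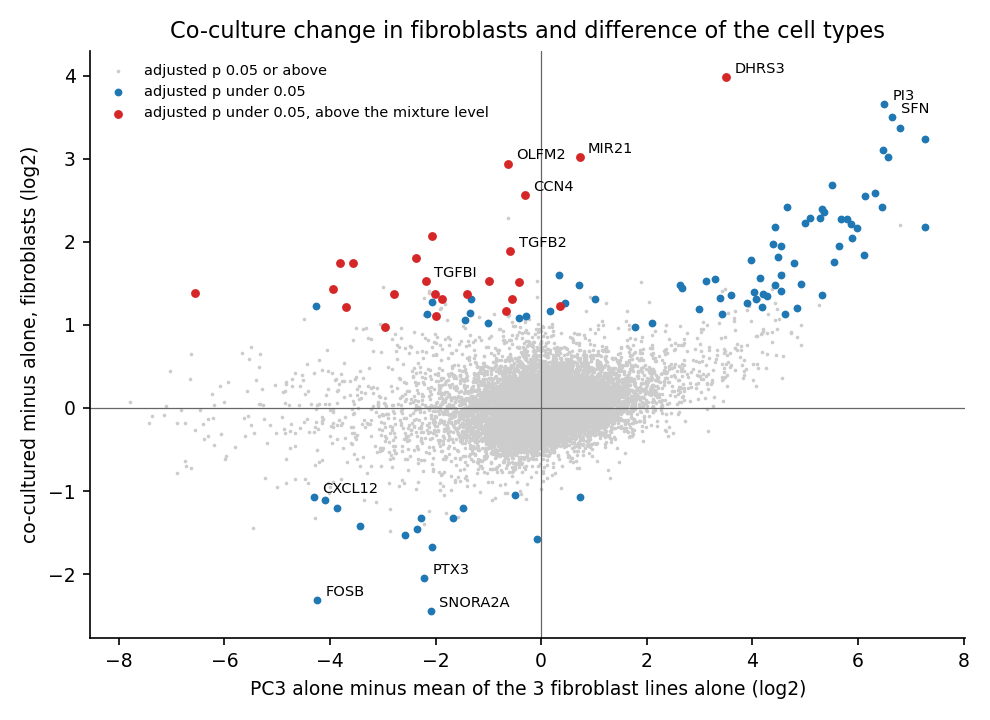
Change of each gene in fibroblasts after co-culture (log2, vertical) against the difference between PC3 alone and fibroblasts alone (log2, horizontal), with 1 point per gene. Genes past the test are blue and the 24 above the mixture level are red, and 57 of the 93 genes that rose lie at 1 or more on the horizontal axis.

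Among the gene lists, collagens and their modifying enzymes were higher in 29 of 34 genes tested (median 0.36). COL5A3 and COL4A1 (1.02) passed over all genes, and adjusted over the list alone 11 rose and 2 fell. The camera adjusted p was 5.78e-08, against an adjusted p = 0.484 with an estimated correlation. SRF targets and contractile genes were higher in 29 of 33 (median 0.20, camera adjusted p = 6.16e-05), none past the test over all genes and 2 adjusted over the list alone, with an adjusted p = 0.484 with an estimated correlation. TGF-beta response genes had TGFB2 and TGFBI up and LRRC15 down (-1.20) among 30 tested, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.484 with an estimated correlation). Inflammatory cytokines had IL1B (1.48) and CCL2 up and CXCL12 down among 28, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.32e-04, and adjusted p = 0.484 with an estimated correlation). IL1B was among the genes at least 1 higher on the log2 scale in PC3 alone and, unlike CCL2, did not lie above the mixture level.

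Heat shock and immediate-early genes were lower in 21 of 28 (median -0.36, camera adjusted p = 5.67e-05). FOSB and ATF3 passed over all genes and 6 fell adjusted over the list alone, while the list had an adjusted p = 0.509 with an estimated correlation. Cell cycle genes were lower in 39 of 49 (median -0.20, with line medians from -0.55 in the knockout to 0.03 in the parental line), none of them past the test over all genes or adjusted over the list alone (camera adjusted p = 7.93e-05, and adjusted p = 0.746 with an estimated correlation). Epithelial markers were higher in 17 of 23 (median 0.22, camera adjusted p = 1.38e-04), with MAL2 (2.18), KRT19 (1.98), SPINT2 (1.37) and CLDN3 (1.27) past the test and 6 adjusted over the list alone. Their adjusted p = 0.484 with an estimated correlation and 0.0320 by fry, and after subtraction of the share of PC3 RNA the camera adjusted p was 0.219.

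In total 109 of 17409 genes passed, 93 higher and 16 lower, and 1915 had an unadjusted p under 0.05 where 870 would be expected by chance. Leaving out either parental array left 0 genes, and leaving out any other array left 22 to 50. DHRS3 had an adjusted p = 0.0562 without the parental array alone and 0.0627 without the co-cultured one, and CXCL12 had 0.128 to 0.303 whichever array was left out. A fit without the block for the line gave 43. Without genes higher in PC3 alone 19 passed, after subtraction of the PC3 share 48 (all among the 109), with the label number as a covariate 67, with an intensity trend 178 and in 1 fit of all 10 arrays 217.

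The knockout line was compared with both other lines to ask what the loss of RHOA changes in fibroblasts. RHOA itself lay at 11.30 (alone) and 11.27 (co-cultured) in the parental line, 11.19 and 11.35 in the virus control, and 10.35 and 10.26 in the knockout. PC3 arrays lay at 11.11 to 11.15. The knockout difference was -0.97 (SE 0.16, lower in 4 of 4 pairs) with an unadjusted p = 3.68e-04 and an adjusted p = 0.0598 over all genes. RHOB and RHOC differed by -0.08 (adjusted p = 0.916) and -0.05 (adjusted p = 0.959). The transcript cluster kept for RHOC lay near background at 3.97 to 4.42, and whether it reads the main transcript was not tested. Its difference therefore says little about RHOC.

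The cadherin gene CDH10 rose by 5.43 in the knockout line (SE 0.20), to 8.29 and 8.65 from 2.86 to 3.20 in the other lines, where it lay below the median of all values (3.43). The protocadherin PCDH7 rose by 3.77 (SE 0.24) and was also higher by 2.15 in the virus control than in the parental line. The mechanically gated channel PIEZO2 rose by 2.42, from 4.26 to 4.57 in the other lines to 6.58 and 7.14, and the growth factor HGF by 2.08. SSX1, a cancer-testis antigen, rose by 2.68, the amino acid transporter SLC6A15 by 2.50 and the leukotriene receptor CYSLTR1 by 2.18. Secreted cytokines rose as well: IL24 by 2.82, the neutrophil chemokine CXCL8 by 2.44, the alarmin IL33 by 2.06 and IL6 by 1.32 (adjusted p = 0.0411). SLC6A15, IL24 and CXCL8 were already higher in the virus control than in the parental line, by 2.18, 2.36 and 2.20.

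TGFB2 fell by 1.73 on the log2 scale (SE 0.16) in the knockout line, with 6.87 against 8.51 and 8.67 alone, and 8.75 against 10.31 and 10.66 after co-culture. Other decreases were -2.88 for WFDC1, -2.07 for PLPPR4, -2.01 for PTGFRN, -1.97 for the myosin MYO1D, -1.93 for RHOJ, -1.87 for SULF1, -1.85 for the actin-binding protein SYNPO2, -1.78 for IRAG1 and -1.72 for the integrin regulator APBB1IP. For several of these the virus control was low too: RHOJ lay at 6.86 and 7.31 in the parental line, 3.99 and 3.94 in the virus control, and 3.65 and 3.55 in the knockout. ACTA2, smooth muscle actin, differed by -1.17 with an adjusted p = 0.124.

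**Figure D3:**
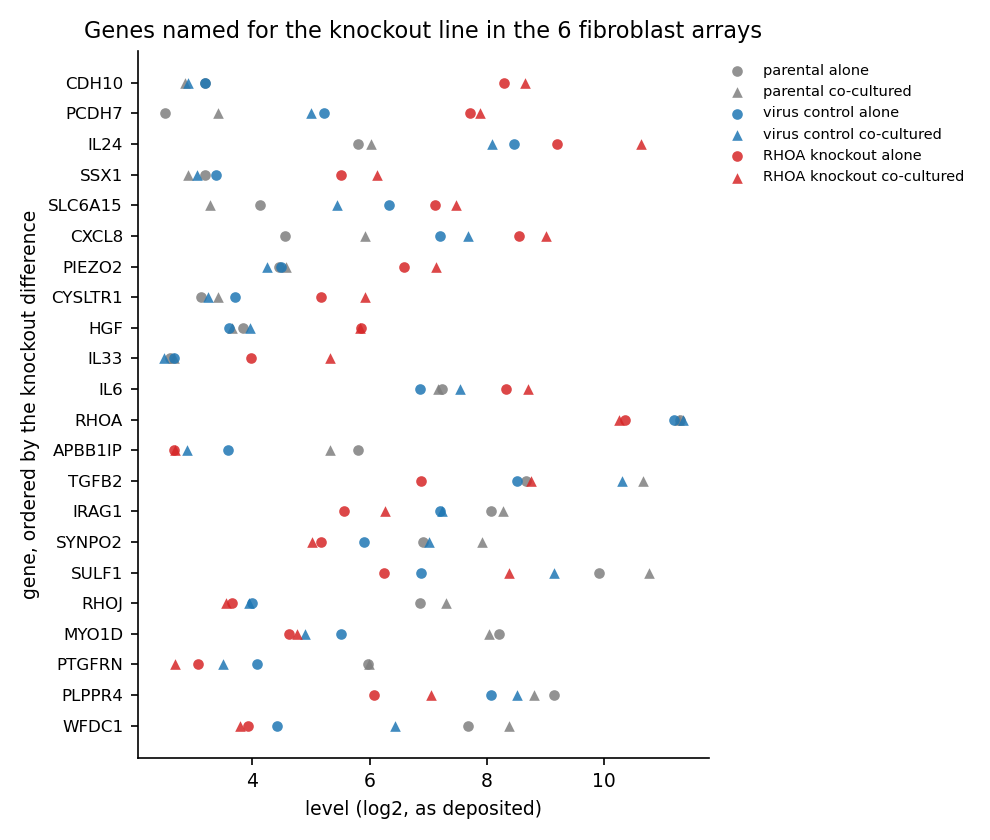
Levels (log2, as deposited) of the genes named for the knockout line, RHOA and IL6 in the 6 fibroblast arrays, circles alone and triangles co-cultured, 1 colour per line. CDH10 lies at 8.29 and 8.65 in the knockout and at 2.86 to 3.20 in the other lines, while RHOJ separates the parental line from both others.

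Inflammatory cytokines and chemokines were higher in 22 of 28 genes in the knockout line (median 0.65). IL24, CXCL8, IL33, CXCL6 (1.85), IL6 and CXCL3 (1.21) passed over all genes, and adjusted over the list alone 15 rose and 1 fell. The camera adjusted p was 3.60e-10, and the list had an adjusted p = 0.604 with an estimated correlation. NF-kB targets were higher in 20 of 28 (median 0.31) with the kinase IRAK2 (1.59) and the feedback inhibitor TNFAIP3 (1.17) past the test and 8 higher and 2 lower adjusted over the list alone. Their camera adjusted p was 1.14e-04, and adjusted p = 0.705 with an estimated correlation. Matrix proteases and inhibitors had the collagenase MMP1 up (1.85) among 25 genes (median 0.15), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.705 with an estimated correlation). Against the virus control alone this list had none adjusted over the list alone (camera adjusted p = 0.304), and MMP1 differed by 0.72.

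Interferon response genes were lower in 38 of 40 (median -0.35), with TRIM22 (-1.35) past the test and 6 lower adjusted over the list alone (camera adjusted p = 4.19e-08, and adjusted p = 0.705 with an estimated correlation). p53 targets were lower in 20 of 24 (median -0.30), with SPATA18 (-1.64), GDF15 (-1.53) and TP53INP1 (-1.02) past the test and 7 adjusted over the list alone (camera adjusted p = 1.10e-06, and adjusted p = 0.604 with an estimated correlation). Contractile and SRF target genes were lower in 24 of 33 (median -0.10), with calponin CNN1 (-1.05) past the test and 5 adjusted over the list alone (camera adjusted p = 8.88e-04, and adjusted p = 0.705 with an estimated correlation). YAP/TEAD targets had a median of -0.26 over 21 genes, with TGFB2 past the test, and 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00390, and adjusted p = 0.705 with an estimated correlation). Against the virus control alone, interferon response genes had 21 of 40 higher (median 0.02, mean -0.01, camera downward with adjusted p = 0.579), p53 targets a median of -0.13 (adjusted p = 0.0960) and contractile and SRF target genes a median of -0.04 (adjusted p = 0.304), so most of the decrease in these 3 lists lay between the parental line and both others.

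In limma 87 genes passed in the knockout comparison, 47 higher and 40 lower, with 1687 at an unadjusted p under 0.05 where 870 would be expected by chance. Leaving out the co-cultured parental array left 0, the parental array alone or the co-cultured knockout array 1, either the knockout array alone or the co-cultured virus control 9, and the virus control alone 19. Without the co-cultured parental array CDH10 had an adjusted p = 0.0590 and TGFB2 0.307. Each culture fitted by itself gave 0, the label number as a covariate 29, an intensity trend 161 and 1 fit of all 10 arrays 199. After subtraction of the PC3 share (4.48% in the knockout, 5.74% and 11.7% in the other lines) 99 passed, 82 of them among the 87.

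Against the virus control alone, which is the closer control for the knockout, 7 genes passed and all were higher. These were CDH10 (5.42, SE 0.23), PCDH7 (2.69), SSX1 (2.60), ADGRL4 (2.58), an adhesion receptor of endothelial cells, PIEZO2 (2.48), HGF (2.06) and PITPNC1 (2.01), a phosphatidylinositol transfer protein. All 7 were also among the 87 genes above, from overlapping arrays. By size, without passing, COL15A1 differed by 2.25 (adjusted p = 0.0525), the phospholipase PLA2G4A by 1.99, PLAC8 by -2.23, ADAM23 by -1.91 and TGFB2 by -1.60 (adjusted p = 0.0525). RHOA differed by -0.96 (adjusted p = 0.198). Inflammatory cytokines were higher in 23 of 28 (median 0.64) with none past the test over all genes and 12 adjusted over the list alone (camera adjusted p = 1.68e-08, and adjusted p = 0.920 with an estimated correlation). NF-kB targets had a median of 0.22 and YAP/TEAD targets of -0.22, each with a camera adjusted p = 0.0118 and an adjusted p = 0.920 with an estimated correlation, with 5 higher and 1 lower of the former and 1 lower of the latter adjusted over the list alone.

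For this comparison 1184 genes had an unadjusted p under 0.05. The count of 7 higher and 0 lower became 9 higher and 2 lower with median centring, 15 genes with an intensity trend and 30 in 1 fit of all 10 arrays. Leaving out either parental array left 0 genes, and leaving out any other array left 1.

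The virus control and the parental line, both with RHOA, were compared to measure how far lines differ without the knockout. The virus control had more BCHE, the butyrylcholinesterase gene (3.15, SE 0.21), ANKRD30B (2.75), the collagenase MMP1 (2.25, SE 0.22), CXCL8 (2.20), SLC6A15 (2.18), PCDH7 (2.15) and osteopontin SPP1 (2.09). LINC01551 (2.48), SORCS1 (2.34) and LRRC17 (2.07) complete the 10 largest increases among the genes that passed and had the same sign in every pair of arrays. It had less GDA, guanine deaminase (-3.15, SE 0.24), the tendon transcription factor MKX (-3.12), RHOJ (-3.12), the focal adhesion protein TES (-3.00), MYO1D (-2.92), FAM180A (-2.84), the potassium channel subunit ABCC9 (-2.65), SAMD5 (-2.58), LCE2A (-2.43) and SBSPON (-2.37). RHOA differed by -0.01 (adjusted p = 0.991).

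Interferon response genes were lower in the virus control in 39 of 40 (median -0.64), including IFIT1 (-1.96, adjusted p = 0.0535), OAS1 (-1.62) and MX1 (-1.47). None passed over all genes and 18 passed adjusted over the list alone (camera adjusted p = 4.89e-15, and adjusted p = 0.741 with an estimated correlation). p53 targets were lower in 21 of 24 (median -0.44), with SPATA18 (-2.32) and TP53INP1 (-1.58) past the test and 8 adjusted over the list alone (camera adjusted p = 4.30e-08, and adjusted p = 0.575 with an estimated correlation). Contractile and SRF target genes were lower in 28 of 33 (median -0.20), with TES past the test, CNN1 at -1.15 (adjusted p = 0.0667) and 6 lower adjusted over the list alone (camera adjusted p = 2.58e-05, and adjusted p = 0.741 with an estimated correlation). Cell cycle genes were higher in 43 of 49 (median 0.26), none past the test or adjusted over the list alone (camera adjusted p = 1.28e-08, and adjusted p = 0.741 with an estimated correlation). In all 58 genes passed, 19 higher and 39 lower, with 1642 at an unadjusted p under 0.05. Leaving out either parental array left 0, either virus control array 8 or 9, and the knockout arrays 29 or 31, while an intensity trend gave 121 and 1 fit of all 10 arrays 165. Of the 87 knockout genes 20 were also among these 58, 19 in the same direction, where 0.29 would be shared by independent lists, though both contrasts use the virus control and parental arrays.

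The next comparison asked whether the knockout line responds to PC3 differently from the other lines. No gene passed in limma, with 1167 at an unadjusted p under 0.05 and a smallest adjusted p of 0.706. Other settings gave 7 genes with renewed quantile normalization or robust eBayes, 2 with cyclic loess and 8 after subtraction of the PC3 share. By size, ANKRD1, a YAP target of the sarcomere and nucleus, went from 7.02 to 4.05 in the knockout line and from 7.28 to 7.86 and 8.01 to 7.74 in the others (difference -3.12, SE 0.43). The proteoglycan VCAN went from 4.68 to 5.05 in the knockout and from 3.84 to 6.85 and 4.12 to 7.62 in the others (-2.88, SE 0.35). In the other direction stood SERPINF1 (3.62), the urea transporter SLC14A1 (3.23), the bradykinin receptor BDKRB2 (2.50), the prostaglandin E synthase PTGES (2.10) and the Notch ligand DLL4 (2.10). Cell cycle genes had a negative difference in 49 of 49 (median -0.48, camera adjusted p = 1.39e-09, and adjusted p = 0.921 with an estimated correlation), none past the test or adjusted over the list alone.

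In PC3 the comparison with PC3 alone asked how tumor cells respond to contact with fibroblasts, and no gene passed. All 3 differences share the 1 array of PC3 alone, so a deviation of that array would move genes and lists alike in all of them. By size, ANKRD1 lay at 6.51 alone and at 3.46, 3.50 and 3.74 after co-culture (-2.94, SE 0.20, adjusted p = 0.0607). The non-coding RNA LINC00520 (-2.83), the hexokinase HKDC1 (-2.78), SAMD3 (-2.35), the BMP-induced inhibitor of differentiation ID1 (-2.51) and the actin-bundling protein LCP1 (-2.05) were lower too. Among the higher genes, IGFBP5 (3.19), COL1A1 (3.03), BGN (3.09), IGFBP7 (2.98), MMP2 (3.05), COL1A2 (2.92) and LUM (2.69) are at high level in fibroblasts, whose RNA made up 0.514% to 4.22% of these arrays by the markers. Of these, COL1A1 and IGFBP7 exceeded the mixture level in all 3 co-cultures, by at least 1.37 and 1.17 over own RNA plus the upper quartile share. Both are among the 50 fibroblast markers that set this quartile, above which some markers lie by construction. The excess therefore does not tell transcription in PC3 from fibroblast RNA. HNRNPA1, an RNA-binding protein, was higher by 2.54 (SE 0.21, adjusted p = 0.0650) and PODXL2, a sialomucin, by 1.94 (SE 0.18, adjusted p = 0.0662). COL1A1, IGFBP7, HNRNPA1 and PODXL2 were among 32 genes above the mixture level in all 3 co-cultures. The transcript cluster kept for HNRNPA1 lay at 5.07 in PC3 alone and at 7.44 to 7.79 after co-culture, and whether it reads the main transcript was not tested.

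Fibroblast markers were higher in 21 of 23 genes in co-cultured PC3 (median 0.65, camera adjusted p = 8.29e-07, and adjusted p = 0.483 with an estimated correlation), with 3 past the test adjusted over the list alone. Cell cycle genes were higher in 43 of 49 (median 0.23, camera adjusted p = 4.34e-06, and adjusted p = 0.483 with an estimated correlation), none past the test adjusted over the list alone. Genes of unfolded protein and amino acid stress were lower in 18 of 26 (median -0.18), with SESN2 at -1.41 and the cystine transporter SLC7A11 at -1.34 and 4 lower adjusted over the list alone (camera adjusted p = 0.00322, and adjusted p = 0.483 with an estimated correlation). Inflammatory cytokines had a median of -0.19 over 22 genes, with IL1A at -1.74, CXCL8 at -1.26 and 5 lower adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.483 with an estimated correlation). Among genes alike in both cell types this list's median was -0.01 and its mean 0.05, with camera pointing upward (adjusted p = 0.932). In limma 0 of 16690 genes passed and 1556 had an unadjusted p under 0.05, where 834 would be expected by chance. Median centring gave 1 gene, no filter 6, a stricter filter 7, an intensity trend 31, 1 fit of all 10 arrays 18 and leaving out fibroblast genes 6.

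PC3 after the knockout line was compared with PC3 after the other lines, to ask whether RHOA in the fibroblasts matters to the tumor cells. MMP1 lay at 8.39 after the knockout and at 4.36 and 5.57 after the others (difference 3.42, SE 0.62), and IL24 at 7.73 against 5.50 and 5.90 (2.03, SE 0.25). IL6 differed by 1.17, CXCR4 by 0.94 and CXCL8 by 0.92. CCL2 (2.80), PTGS2 (2.30), MXRA5 (1.96), MMP3 (1.51) and C3 (2.03) were higher by size too, while SAMD10 (-1.46), CYP2J2 (-1.27), SIGLEC15 (-1.23) and PI3 (-1.27) were lower. The knockout fibroblasts themselves held MMP1 at 11.36, IL24 at 10.62 and CCL2 at 11.88 after co-culture, and the fibroblast share was 4.22% in this PC3 array against 0.514% and 3.77%. CCL2, PTGS2 and MXRA5 are themselves among the 50 fibroblast markers. In this array PTGS2 and MXRA5 implied shares of 6.06% and 5.30%, within the marker quartiles (3.27% and 6.93%), and CCL2 implied 22.5%. Matrix genes other than collagens were higher in 25 of 31 (median 0.28). PC3 after the knockout line is 1 array, so a deviation of that array could not be told from an effect of the fibroblast line, for genes or lists. None of the 16690 genes passed in limma (smallest adjusted p = 0.757, with 922 at an unadjusted p under 0.05), and the count was 0 under every alternative tried for it, from normalization and filter to variance model and subtraction.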

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

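Of the tests below, the fit with the label number as a covariate, the regrouping of arrays and the list tests without subtraction were fixed beforehand, and the others were chosen only after the result was seen. Genes that PC3 expresses more than fibroblasts were common among those that rose in co-cultured fibroblasts, with DHRS3 (3.98), PI3 (3.66) and SFN (3.50) at the top. RNA of PC3 cells left in the sorted fibroblasts is a candidate explanation, and 97.1% of the 35 genes among them not used to estimate the share of PC3 RNA lay less than 1 on the log2 scale above own RNA plus the upper quartile share in at least 1 line, all but DHRS3. Over own RNA plus the median share the median excess of these 35 was 0.46, which leaves open whether fibroblasts may also have transcribed some of them.

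The 24 genes that exceeded the mixture level included TGFB2, TGFBI, CCN4 and CCL2. RNA of PC3 cells is argued against for 21 of them, which lay above both their own line and all PC3 arrays in all 3 lines by more than the distance from the change to its lower 95% limit, where no share of PC3 RNA can take a gene. How these genes were picked already placed most of them above their own line, which that distance does not allow for. The other 3 (TGFB2, DHRS3 and ADAMTS15) did not exceed the highest PC3 array by more than that distance in at least 1 line. Levels so near or above it would take mostly PC3 RNA, against upper quartile shares of 13.8%, 6.92% and 6.17%. Over own RNA plus that share the smallest excess was 2.67 for DHRS3, 1.84 for TGFB2 and 1.04 for ADAMTS15. At the marker shares this argues against PC3 RNA for them too, though they were picked for an excess of at least 1. DHRS3 (7.74 to 8.02 against at most 7.37) and ADAMTS15 (5.81 to 6.78 against at most 5.64) lay above every PC3 array in all 3 lines. TGFB2 reached 10.66 and 10.31 in the parental and virus control lines, against at most 8.90 in PC3. In those lines this argues against PC3 RNA at any share, while TGFB2 lay at 8.75 in the knockout. A difference tied to the number at the end of the label codes is argued against as the whole cause. For this, 35 genes above the mixture level in the parental and knockout lines were picked without the virus control. In the virus control, where the number runs the other way, 34 of them exceeded own RNA plus the upper quartile share too (median 1.33, 95% limits 1.13 and 1.67). These limits, from a Wilcoxon test, measure the spread between genes read from 1 pair of arrays, not how far that pair would vary if repeated. With the label number as a covariate the 24 genes had a median change of 1.47 and 14 still passed (median SE 0.21 instead of 0.18), but this follows in part from how they were picked. Handling of the sorted cells might also change expression (the heat shock and immediate-early list had a median of -0.36), and this stays open because the sample descriptions give the same protocol for all arrays and do not settle whether cells grown alone were sorted too.

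Genes past the test in the knockout line, such as CDH10 and CXCL8, might reflect RNA of PC3 cells. Against this, 94.3% of them passed again after subtraction of the PC3 share, CDH10 among them. CXCL8 was left out of that fit, as were all genes with most of their signal from PC3. In the other settings, each culture fitted by itself among them, the knockout difference of CXCL8 was 2.20 to 2.67. Cells grown alone had no contact with PC3. Among the co-cultured fibroblasts the knockout line had the smallest share of PC3 RNA (4.48% against 5.74% and 11.7%). For CXCL8 these values argue against PC3 RNA as the cause of the difference. Differences between lines that have nothing to do with RHOA could also give genes past the test in the knockout line. Between the 2 lines that have RHOA, 58 genes passed. With 1 knockout line, line and knockout cannot be separated. RHOA RNA at 10.35 and 10.26 in the knockout line leaves open how much protein was lost.

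Regrouping the 6 fibroblast arrays into 2 sets of 3 gave 10 splits, too few splits for a share under 0.05. In 1 of the 10, the real one, 109 genes passed, and the highest other count was 0. Most other splits parted only 1 line and so rested on 1 pair of arrays, and in the rest the co-culture effect entered the spread. A low count was therefore likely in them from the design, and no conclusion is drawn from it.

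The lists below stood out because camera found their co-culture response to differ between the knockout line and the other lines, although no gene of any list passed the test over all genes, and adjusted over the list alone only 1 gene each did among NF-kB targets, cytokines and matrix genes other than collagens. Cell cycle genes had a median difference of -0.48 over 49 genes, with all 49 negative. NF-kB targets and inflammatory signalling had a median difference of 0.43, with 24 of 28 positive. Inflammatory cytokines and chemokines had 0.49, with 19 of 28 positive (camera adjusted p = 3.19e-04). Fibroblast markers had 0.32, with 21 of 27 positive (camera adjusted p = 0.00862). Unfolded protein and amino acid stress genes had -0.24, with 22 of 26 negative (camera adjusted p = 0.0104). Collagens and their modifying enzymes had 0.15, with 26 of 34 positive (camera adjusted p = 0.0107). The other matrix genes had 0.32, with 23 of 35 positive (camera adjusted p = 0.0125). Interferon response genes had 0.22, with 29 of 40 positive (camera adjusted p = 0.0199). Antigen presentation genes had 0.34, with 14 of 20 positive (camera adjusted p = 0.0415). Each of these lists had an adjusted p = 0.921 with an estimated correlation. Among members alike in both cell types, the camera adjusted p was 1.26e-09 for cell cycle genes, 8.96e-04 for cytokines and 0.00752 for NF-kB targets, but 0.0679 for the stress genes, 0.349 for interferon response, 0.422 for antigen presentation, 0.779 for collagens (median -0.0025) and 0.887 for the other matrix genes. The share of PC3 RNA was 11.7% in the parental line against 4.48% in the knockout, and after its subtraction the camera adjusted p was 0.0441 for collagens, interferon response and fibroblast markers and 0.0735 for the other matrix genes and antigen presentation.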

How the results depend on the processing

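Of the settings below, subtraction of the other cell type's share was chosen only after the result was seen, and all other tests were fixed before the data were examined. No named gene past the test in a fibroblast comparison changed sign in any alternative that kept it among the genes tested, while the number of genes past the test moved widely. The rule picked genes with the same sign in every pair of arrays. For co-culture, leaving out an array or a line therefore could not change the sign of genes picked by the rule. The results of single named genes stayed past the test in 503 cases and lost it in 332 for co-culture, 348 and 237 for the knockout, 80 and 38 for the knockout against the virus control, and 279 and 92 for the virus control against the parental line. An intensity trend gave 178 genes for the fibroblast co-culture effect (109 as reported), 161 for the knockout (87), 15 for the knockout against the virus control (7), 121 for the virus control against the parental line (58) and 31 for PC3 after co-culture (0). A single fit of all 10 arrays gave 217, 199, 30, 165 and 18 in the same order. The label number as a covariate gave 67 for co-culture and 29 for the knockout. The cause of these shifts was not tested. Median centring gave 11 genes for the knockout against the virus control and 1 for PC3 after co-culture, averaging the transcript clusters of a gene gave 11 for the former, and robust eBayes gave 11 for it and 7 for the difference in response (0 as reported). Renewed quantile normalization gave 7 and cyclic loess 2 for that difference. For PC3 after co-culture, no filter gave 6 and a stricter filter 7. For these the cause was not tested. Without the block for the line 43 genes passed for co-culture, because differences between lines then enter the spread. Leaving out genes of the other cell type gave 19 for fibroblasts and 6 for PC3, where fewer genes were tested. Subtraction of the other cell type's share gave 48 for co-culture, 11 for the knockout against the virus control and 8 for the difference in response, with fewer genes tested as well.

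Cells alone and co-cultured cells fitted separately gave 0 genes each for the knockout, with fewer arrays in each fit. With 1 array left out, and so fewer arrays, the count ranged from 0 to 50 for co-culture, from 0 to 19 for the knockout, from 0 to 1 for the knockout against the virus control and from 0 to 31 for the virus control against the parental line. Leaving out the parental line gave 0 for co-culture, the virus control 34 and the knockout line 42.

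Signs changed for the genes below, none of them past the test, and for 2 gene lists that camera had called. With 1 array left out, the co-culture change of RHOA in fibroblasts ranged from -0.06 to 0.065 and that of CXCR4 from -0.12 to 0.13 (-0.17 after subtraction). The knockout difference ranged from -0.20 to 0.035 for RHOB (0.035 in cells alone) and from -0.15 to 0.0538 for RHOC. Against the virus control it ranged from -0.18 to 0.0575 for RHOB, from -0.33 to 0.0825 for RHOC and from -0.05 to 0.15 for CXCL12. Between the virus control and the parental line the range was -0.13 to 0.10 for RHOA (0.00875 with renewed quantile normalization), -0.14 to 0.0475 for RHOB and -0.0575 to 0.36 for RHOC. In PC3 after co-culture it was -0.015 to 0.005 for RHOA (0.00101 after subtraction), -0.32 to 0.14 for RHOB, -0.06 to 0.025 for RHOC and -0.47 to 0.16 for ACTA2. Among members alike in both cell types, the PC3 medians were 0.20 for YAP/TEAD targets and -0.01 for inflammatory cytokines and chemokines, where camera pointed the other way with fewer genes. With such members alone 31 list calls stayed and 28 were lost, and after subtraction 53 stayed and 13 were lost. With an estimated correlation all 66 were lost, and by fry 65, all but the epithelial markers in co-cultured fibroblasts. Apart from fewer arrays or genes, the cause was not tested.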

Other observations

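The genes and groups in this part, the mixture level and the implied shares were chosen only after the result was seen, while the tests of single genes were planned. Several genes in co-cultured PC3, picked after their values were seen from the 32 above the mixture level, lay above both PC3 alone and the estimated mixture. The transcript cluster kept for the glycolytic enzyme ENO1 was higher by 1.71 (SE 0.20), from 6.17 alone to at most 8.03, and its intronic transcript ENO1-IT1 by 1.90. The small nucleolar host gene SNHG1 was higher by 1.81 (SE 0.19). Those kept for the ribosomal protein genes RPL32 and RPS25 were higher by 1.37 and 1.26, from 4.35 and 6.38 in PC3 alone. Transcript clusters with several symbols were left out, so whether those kept read the main transcript of these genes was not tested. Below both cell types lay 6 genes, among them ID1, ID3 and HMOX1. ID1 went from 10.78 to 8.60, 8.07 and 8.14, while ID3 differed by -1.47 and heme oxygenase HMOX1 by -1.45. None of these passed the test, and all rest on the 1 array of PC3 alone.

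Small nucleolar and Cajal body RNAs did not move as a group in co-cultured fibroblasts, where 192 were tested, 90 were higher and 102 lower, with 1 that passed upward (SNORD114-17, 1.38) and 3 downward, SNORA2A and SCARNA3 among them, and 10 higher and 7 lower adjusted over the list alone. In PC3 after the knockout line 137 of 178 were higher than after the other lines, and in the virus control 135 of 192 were higher than in the parental line. Fibroblast genes gave unequal traces in PC3. COL1A1 implied shares of 7.41%, 17.9% and 21.9% after the parental, virus control and knockout lines and TERT 1.20%, 6.20% and 8.58%, against marker medians of 0.514%, 3.77% and 4.22%. COL1A1 and TERT are themselves among these markers.

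Beyond the named genes, 29746 transcript clusters had no symbol or several, 16739 of them passed the filter in fibroblasts, and 0 passed the test for co-culture in limma, with 1379 at an unadjusted p under 0.05. In each array 48.6% to 50.4% of transcript clusters lay below 3.43, so signal over background limits what can be said of genes with low values, such as RHOC. A low value of the transcript cluster kept need not mean weak expression of the gene. Sorting purity, protein levels and secretion of CXCL12 or CXCL8 were not measured in these data.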
